A study of Homo sapiens with 9 samples.

How the data were processed

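Total RNA of Hec50 cells was extracted with Trizol, labelled with biotin and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The labels place 3 arrays in each of 3 groups: mock transfection, scrambled negative control and miR-200c mimic. They do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Between replicates of a group the SD of the differences over genes was 0.111 to 0.148 on the log2 scale, and 2.24% to 2.86% of genes held identical values.

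The deposited values are log2 expression, 1 table of 54675 probe sets by 9 arrays. How the authors summarised and normalised the probes is not given in the sources used here. From the values, the authors' log2 table is centred: the median over the 9 arrays was exactly 0 in 100.0% of probe sets, and every array's median over probe sets was 0. In 48.89% of probe sets more than 1 of the 9 values was exactly 0. Such ties can lower the spread between arrays, and their origin is not known. The centring removed the original level. The level class was recovered from the rounding left by single precision storage, since the step between stored numbers doubles at 4 and 8. By this, 27.32% of probe sets had a median of 8 or more on the log2 scale, 54.97% lay from 4 to 8, 17.63% lay below 4, and 0.08% could not be placed. On 6000 simulated probe sets 97.9% of classes were recovered. These step sizes depend on the size of the stored number alone, so they do not test the base of the logarithm. Signal over background is not known for these arrays, so a low class does not say that a gene was undetected.

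Gene names came from the platform's annotation of 2016, checked by Entrez identifier against a table of human genes on assembly GRCh38.p14, which was used for names alone. After 62 control probe sets were left out, 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none. Of the former, 41037 had their identifier in that table, and 0 symbols differed from it. Whether the symbols had been brought up to date beforehand is not known, so names later than 2016 may stand among them. Only probe sets with 1 symbol were used for genes, giving 19775 genes, of which 10523 had more than 1 probe set. The plan named the probe set with the highest mean for each gene. Centred values have no such mean, so the mean of the gene's probe sets in its highest level class was used.

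Group means were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), which shares 1 estimate of the spread, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were mimic against scrambled control, mimic against mock, scrambled control against mock, and mimic against the mean of both controls. The median standard error of a difference between 2 groups was 0.0588. Standard errors in the text are those of log2 changes. On simulated data for mimic against scrambled control, 5 runs with 200 changed genes among 19775, the fit recovered 98.2%, 99.7% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, and 53 of 1046 calls were false (5.07%). The simulated noise was normal, independent between genes and arrays, and of the fit's own spread. The simulation therefore checks the fit and says nothing of noise that real arrays or genes share.

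The tests, the alternatives (except those said below to be chosen after), the rule for named genes and 19 gene lists were fixed before the data were examined, and the summary by level class was chosen after. The lists cover published targets of the miR-200 family, genes named by the same group, transition factors, epithelial and mesenchymal markers, actin, matrix and integrins, tubulin, survival and neurotrophin receptors, Notch and polycomb, TGF-beta, cell cycle, interferon and double-stranded RNA response, cholesterol and fatty acids, unfolded protein and stress response, small RNA machinery, hormone response, leukocytes and endothelium. They were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison), and again with an estimated correlation and with fry. Lists share members: 33 of the 67 measured published targets stand in another list, 4 of them among the genes of the same group, and without those 4 camera gave an adjusted p of 3.73e-07 for mimic against scrambled control, an alternative chosen after seeing the data. That is with the preset correlation, and the whole list did not pass with an estimated one (adjusted p = 0.115 with an estimated correlation). Camera results in the text are preset unless an estimated correlation is named.

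Named genes are, per comparison, the 8 largest rises and the 8 largest falls among called genes whose 3 arrays of 1 group lie beyond the 3 of the other, up to 4 members of each list with the smallest p in mimic against scrambled control, and ZEB1, ZEB2, CDH1, VIM, FN1, MSN, TUBB3, NTRK2, LEPR and ARHGAP19. Not every gene that the rule takes is printed, and genes named outside it are said to have been chosen after their values were seen.

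Alternatives were the replicate number as a block, quantile normalization, centring each array on its median, the mean of all probe sets of a gene, every probe set, an intensity trend with a robust prior, only the arrays compared, array weights, a fold of at least 1.5, and leaving out each array. The planned filters on low values needed uncentred levels and were replaced by filters on the recovered class (8 or more, 4 or more), and a fit without 2 arrays that deviate together was added, both after seeing the data. A pseudocount was not tried because the values are already logs, and the search for miR-200c seed matches was not run because no transcript sequence was used here. The trend works on the mean of centred values and so carries little meaning. Quantile normalization too was run on centred values. The SD over genes was 0.1506 to 0.1627 on the mimic arrays and 0.0961 to 0.1212 on the other arrays. Giving all arrays the same distribution therefore shrinks large changes with the mimic by construction, and can stretch those between the controls. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 prepared the tables, and matplotlib 3.10.9 drew the plots.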

Results

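Gene expression was measured in Hec50 cells, an established human endometrial cancer line, on 9 Affymetrix arrays that carry 54675 probe sets. Of these arrays, 3 held RNA of mock transfected cells, 3 held RNA of cells given a scrambled negative control, and 3 held RNA of cells given a synthetic mimic of miR-200c. Both RNAs were used at 60 nM for 48 hours. The labels give no time for the mock transfected cells. miR-200c is a microRNA of the miR-200 family, which is abundant in epithelial cells and pairs with sites in ZEB1 and ZEB2 mRNA. The study asked which genes respond when this microRNA is put back into an aggressive cancer line. The values are log2 expression centred on each probe set's median over the 9 arrays, so they show differences between groups and not levels. Tests were run on 19775 genes, and the number of arrays limits the precision.

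The comparison of the mimic with the scrambled control sets 2 groups side by side that received a small RNA at the same dose. A response to the scrambled sequence would enter it together with that to miR-200c, and was not tested apart. CDH1, which encodes the epithelial adhesion protein E-cadherin, was 9.57-fold higher with the mimic (log2 change 3.26, SE 0.12, n = 3 per group, limma adjusted p = 8.41e-08). That value rests on 1 of its 2 probe sets, the other was higher by 0.58 on the log2 scale, and CDH1 had a log2 change of 1.92 with the mean of both and of 1.69 after quantile normalization. Quantile normalization of centred values shrinks large changes with the mimic by construction. ZEB1, a transcriptional repressor of CDH1, was 2.96-fold lower (log2 change -1.57, SE 0.06, adjusted p = 1.52e-07), and its relative ZEB2 was 1.48-fold lower (log2 change -0.56, SE 0.07, adjusted p = 0.000312). The fibronectin gene FN1 was 1.98-fold lower and the vimentin gene VIM 1.17-fold lower (adjusted p = 2.06e-06 and 0.0045). Over all genes, 1514 were higher and 1399 lower with the mimic, of which 187 and 111 changed by at least 1.5-fold. Without mimic replicate 1 there were 1153 higher and 1314 lower, and at a level of 8 or more 1293 and 1451.

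After CDH1, the largest rises were those of SCGB2A1, a secretoglobin (3.40-fold), ZBED2 (3.32-fold), the teneurin gene TENM2 (3.18-fold), MAL2, a protein of apical membrane traffic (3.14-fold), CDS1 (3.08-fold), ARL14 (3.06-fold) and ARHGDIB (3.04-fold). The standard errors of these log2 changes lay between 0.05 and 0.13, and the highest adjusted p was 1e-05. OSTM1 fell furthest, by 1.97 on the log2 scale (3.91-fold, SE 0.06, adjusted p = 6.58e-08). SEC23A, a component of the COPII coat of secretory vesicles, was 2.71-fold lower (SE 0.05). The receptor tyrosine kinase gene EPHB1 was 2.69-fold lower, the glycosyltransferase genes POGLUT2 and B4GAT1 were 2.61-fold and 2.42-fold lower, MAL was 2.10-fold lower and ZCCHC24 was 2.06-fold lower, each with an adjusted p of at most 5.52e-05. Genes with these largest changes were taken from those whose 3 arrays of 1 group lay beyond the 3 of the other. Probe sets of a gene could disagree: those called lower were 3 of 4 for ZEB1, 2 of 5 for ZEB2, 4 of 7 for FN1, 1 of 2 for B4GAT1, 1 of 4 for PDGFRA and 3 of 6 for NTRK2, and those called higher were 3 of 4 for CDS1 and 2 of 3 for ARHGDIB. With the mean of all probe sets, 22 of 74 called changes of named genes were over 1.5 times smaller on the log2 scale, among them ZEB1 (-0.99), ZEB2 (-0.21), ARHGDIB (1.01), EPHB1 (-0.85), B4GAT1 (-0.67), PPM1F (-0.47), PDGFRA (-0.22), ITGB8 (0.48), EPSTI1 (0.65), NOTCH3 (-0.40), LFNG (-0.38), NOTCH1 (-0.34) and JAG1 (-0.14). After quantile normalization 6 were, with MAL2, CDS1, ARL14 and ARHGDIB at 1.01 to 1.02 and EPCAM at 0.66 beside CDH1.

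**Figure D1:**
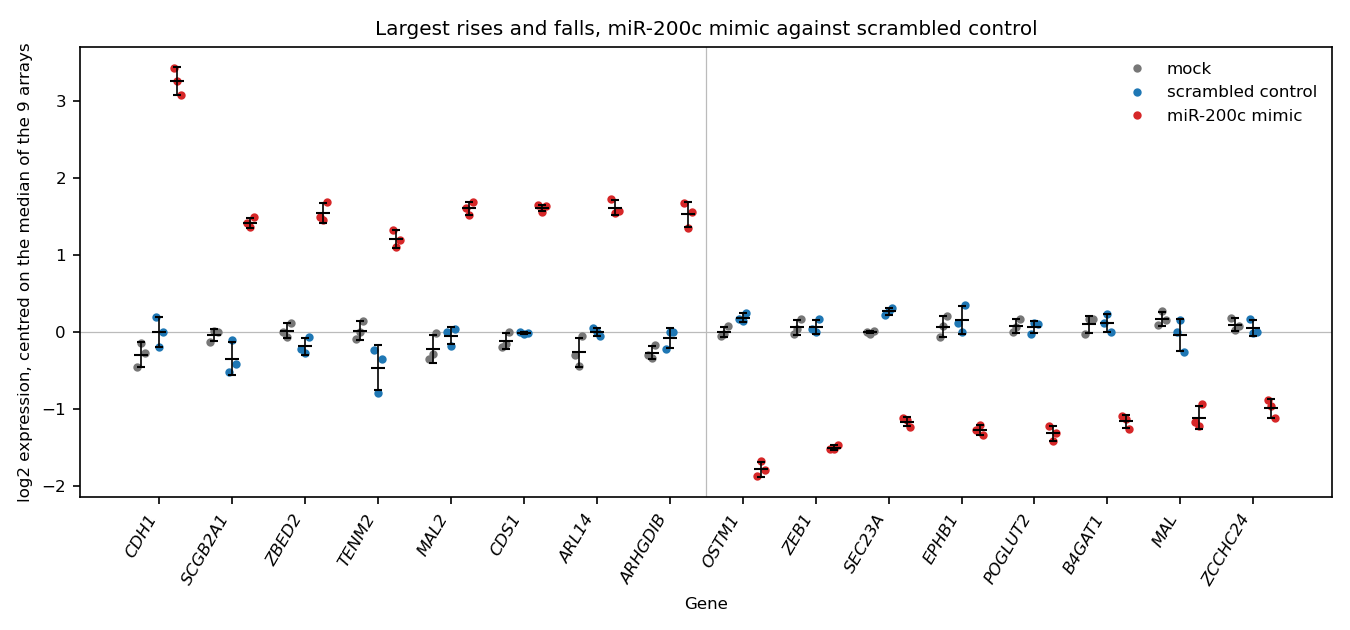
Log2 expression of 16 genes on each of the 9 arrays, centred on the median of the arrays, with points for arrays and bars for the mean and SD of 3 arrays per group. CDH1 averaged 3.26 with the mimic against 0.00 with the scrambled control and -0.29 in mock transfected cells, and ZEB1 averaged -1.50, 0.07 and 0.06.

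Of 61 measured epithelial markers, 34 were higher with the mimic, 0 were lower and 27 did not pass, and adjusted over the list alone 35 were higher and 1 lower. Besides CDH1 and CDS1, the laminin gene LAMB3 rose by 1.38 on the log2 scale (SE 0.05) and the adhesion gene EPCAM by 1.06 (SE 0.05). The list stood higher than other genes (camera adjusted p = 1.69e-18), also with the correlation between genes estimated from the data (adjusted p = 0.00586 with an estimated correlation).

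Of 67 measured published targets of the miR-200 family, taken from studies of other cell lines, 2 were higher, 30 lower and 35 did not pass. Among the 67 are 4 that the same group also named, ZEB1 and PPM1F included, so the list is not wholly independent of these arrays. Adjusted over the list alone 7 were higher and 34 lower (camera adjusted p = 1.59e-09, adjusted p = 0.115 with an estimated correlation). Besides SEC23A and ZEB1, the phosphatase gene PPM1F fell by 0.89 (SE 0.05) and the cofilin gene CFL2 by 0.79 (SE 0.05) on the log2 scale. TGFB2 was 1 of the 2 that rose, by 0.72 (SE 0.05). Of 9 genes that the same group has named as responsive to miR-200c, among them ZEB1, FN1 and PPM1F, 7 were lower, 0 higher and 2 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 2.17e-09, adjusted p = 0.00586 with an estimated correlation). These genes were chosen at least in part on these arrays and are not independent evidence of their direction. ARHGAP19 fell by 0.73 (SE 0.05), the ezrin family gene MSN by 0.51 (SE 0.04) and the neurotrophin receptor gene NTRK2 by 0.46 (SE 0.09). MSN was called on 1 of its 2 probe sets, and with the mean of both its log2 change was -0.18 (adjusted p = 0.0631, the highest of 17 alternatives that began at 9.39e-06). The class III beta-tubulin gene TUBB3 had a log2 change of 0.02 (SE 0.05, adjusted p = 0.824) and the leptin receptor gene LEPR one of 0.04 (SE 0.07, adjusted p = 0.744). LEPR was measured here by 1 probe set, at a level of 4 to 8, so this does not show that its RNA was unchanged.

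Among regulators of actin and motility, 7 of 79 were higher, 18 lower and 54 did not pass, and adjusted over the list alone 9 were higher and 20 lower (camera adjusted p = 0.00128, adjusted p = 0.497 with an estimated correlation). ARPC1A, a subunit of the Arp2/3 complex, fell by 0.92 (SE 0.05). Of 52 mesenchymal markers, 3 were higher, 13 lower and 36 did not pass, with 3 and 13 adjusted over the list alone (camera adjusted p = 0.0258, adjusted p = 0.613 with an estimated correlation). The platelet-derived growth factor receptor gene PDGFRA fell by 0.41 (SE 0.06), and IGFBP3, an insulin-like growth factor binding protein, rose by 0.66 (SE 0.05). The call of the mesenchymal list ended after quantile normalization (adjusted p = 0.0589), with the mean of all probe sets (0.0622), among genes at a level of 8 or more (0.162) and without mimic replicate 2 (0.0688). Over 16 alternatives its adjusted p lay between 0.012 and 0.613. Of 16 transcription factors of the epithelial to mesenchymal transition, ZEB1, ZEB2 and SOX9 were lower, 0 were higher and 13 did not pass, both over all genes and adjusted over the list alone (camera adjusted p = 0.0792).

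Of 51 measured interferon-stimulated genes and sensors of double-stranded RNA, 18 were higher with the mimic than with the scrambled control, 1 was lower and 32 did not pass. Adjusted over the list alone 18 were higher and 2 lower (camera adjusted p = 7.37e-07, adjusted p = 0.265 with an estimated correlation). EPSTI1 rose by 1.03 (SE 0.08), IRF9, a subunit of the complex that drives interferon-stimulated genes, by 0.94 (SE 0.10), DTX3L by 0.50 (SE 0.05) and HERC5 by 0.47 (SE 0.05). Of 26 unfolded protein and stress response genes, 11 were higher, 3 lower and 12 did not pass, with 13 and 4 adjusted over the list alone (camera adjusted p = 0.00899, adjusted p = 0.666 with an estimated correlation). The co-chaperone gene DNAJB1 rose by 0.48 (SE 0.05), while NQO1, a quinone reductase gene, had a log2 change of -0.37 (SE 0.05). The stress call also ended with the mean of all probe sets (adjusted p = 0.0622) and without both mock replicate 3 and mimic replicate 1 (0.0594), and over 16 alternatives its adjusted p lay between 0.00364 and 0.666. Against mock the stress list held 6 higher and 6 lower, and the 2 probe sets of DNAJB1 were at -0.06 and 0.01. Of the 4 interferon genes, EPSTI1 was at 0.64 against mock, IRF9 at 0.34, HERC5 at 0.25 and DTX3L at 0.16.

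Matrix and integrin genes held 12 higher, 15 lower and 42 not passed of 69 (14 and 16 adjusted over the list alone, camera adjusted p = 0.724, and 12 higher and 10 lower after quantile normalization). The integrin gene ITGB8 rose by 1.05 on the log2 scale, and CRTAP had a log2 change of -0.80. TGF-beta pathway genes held 9 higher, 2 lower and 23 not passed of 34 (12 and 6 adjusted over the list alone, camera adjusted p = 0.0792), with the receptor genes ACVR2A higher (0.40) and TGFBR3 lower (-0.58). Of 27 cholesterol and fatty acid genes, 4 were higher, 1 lower and 22 not passed (5 and 1 adjusted over the list alone, camera adjusted p = 0.165), with the sterol transfer gene STARD4 at 0.51. Without mimic replicate 3 the TGF-beta and cholesterol lists passed as higher (adjusted p = 0.0344 and 0.046), and over 16 alternatives each their highest adjusted p were 0.852 and 0.763. Notch and polycomb genes held 1 higher, 4 lower and 23 not passed of 28, the same for both directions adjusted over the list alone (camera adjusted p = 0.446), and NOTCH3 (-0.72), LFNG (-0.63), NOTCH1 (-0.52) and JAG1 (-0.26) were the 4.

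Survival and neurotrophin receptor genes held 7 higher, 6 lower and 14 not passed of 27 (7 and 6 adjusted over the list alone, camera adjusted p = 0.724), with a median of -0.03, a mean of 0.02 and a test that pointed higher. BIK, a proapoptotic gene, was at 0.52 and the neurotrophin gene BDNF at 0.40. Tubulin and microtubule genes held 5 higher, 7 lower and 16 not passed of 28 (6 and 8 adjusted over the list alone, 0.77), with TUBB4A at -0.47 and MAP7 at 0.45. Cell cycle genes held 9 higher, 9 lower and 48 not passed of 66 (9 and 10 adjusted over the list alone, 0.703), with the phosphatase gene CDC25B at -0.66 and the inhibitor gene CDKN1A at 0.33. Small RNA machinery held 3 higher, 1 lower and 8 not passed of 12 (3 and 1 adjusted over the list alone, 0.62), with DICER1 at 0.34. Hormone response genes held 1 higher, 4 lower and 14 not passed of 19 (2 and 5 adjusted over the list alone, 0.724), with MUC1 at 0.61 and WT1 at -0.44. Markers of leukocytes held 0 higher, 1 lower (LAPTM5, -0.22) and 17 not passed of 18, and markers of endothelium 0 higher, 1 lower (ENG, -0.41) and 15 not passed of 16. Adjusted over the list alone the counts of both were the same (camera adjusted p = 0.724 and 0.746). The call of ENG ended with the mean of its probe sets (adjusted p = 0.51, the highest of 17 alternatives that began at 0.00145).

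**Figure D2:**
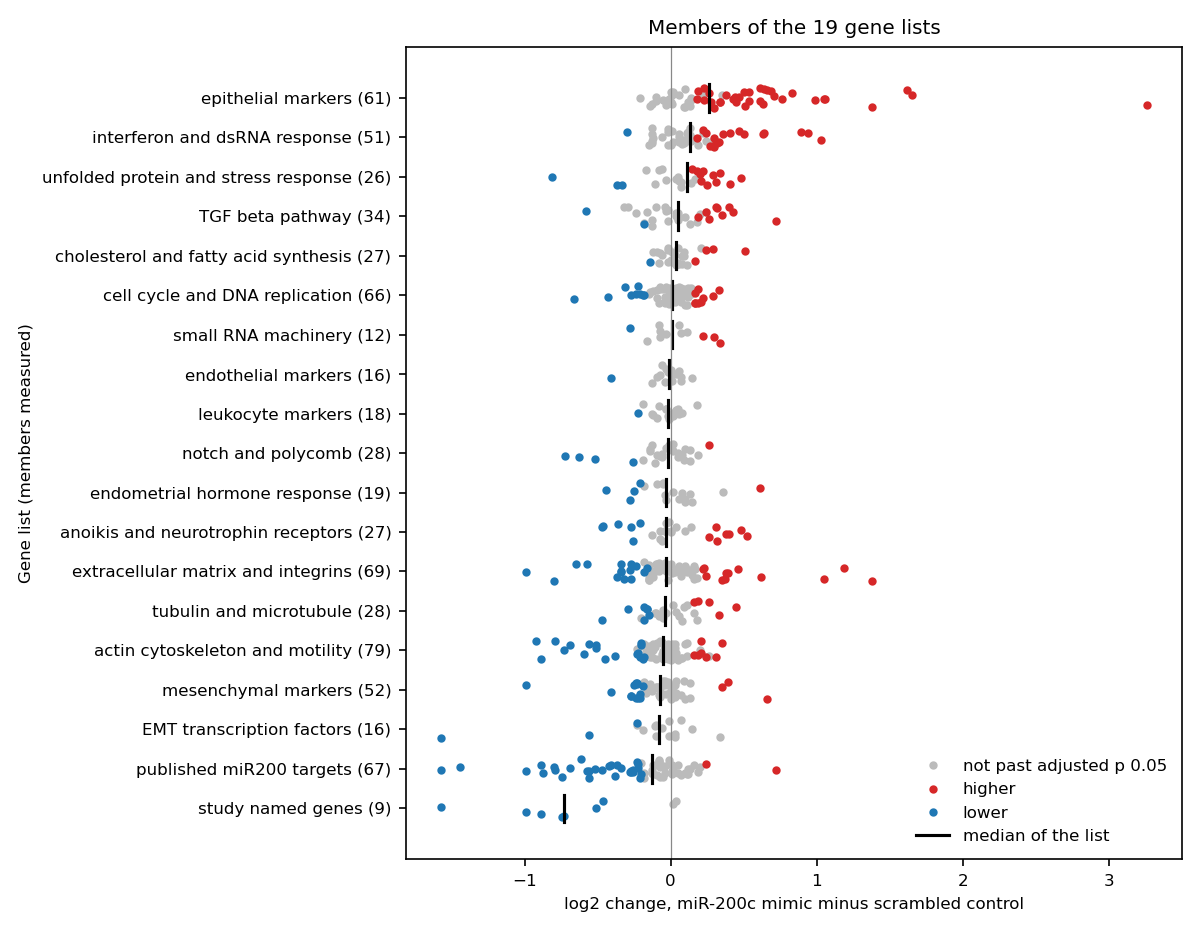
Log2 change of each measured member of the 19 gene lists, mimic minus scrambled control, with genes past adjusted p 0.05 in red (higher) and blue (lower), the rest in grey, and the list median as a black line. The epithelial list has its median at 0.26 with 34 higher and 0 lower members, and the published targets at -0.13 with 2 higher and 30 lower.

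Mock transfected cells received no RNA, so the comparison of the mimic with mock holds the response to the mimic together with that to adding a small RNA. CDH1 was 11.7-fold higher than in mock (log2 change 3.55, SE 0.12, adjusted p = 4.79e-08, and 2.01 with the mean of both probe sets), and ENPP5, of the ectonucleotide pyrophosphatase family, was 3.44-fold higher (SE 0.05). ZEB1 was 2.95-fold lower (SE 0.06), the heme oxygenase gene HMOX1 2.93-fold lower (SE 0.12), FN1 2.75-fold lower (SE 0.06) and RIPPLY1 2.54-fold lower (SE 0.15). In all, 1662 genes were higher and 2038 lower, of which 151 and 156 changed by at least 1.5-fold. ZEB2 (-0.85), NTRK2 (-0.76), MSN (-0.68), VIM (-0.35) and TUBB3 (-0.28, SE 0.05, adjusted p = 0.00341) were lower than in mock. With the mean of all probe sets ZEB2 was at -0.32 and MSN at -0.27. LEPR had a log2 change of 0.10 (adjusted p = 0.397) and passed without mimic replicate 1 (0.18, adjusted p = 0.0248, the lowest of 17 alternatives that reached 0.801).

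Epithelial markers were higher than in mock in 32 of 61, lower in 2 and not passed in 27, with 37 and 2 adjusted over the list alone (camera adjusted p = 8.6e-15, adjusted p = 0.00699 with an estimated correlation). Published targets were higher in 3, lower in 31 and not passed in 33 of 67, with 3 and 35 adjusted over the list alone (camera adjusted p = 6.59e-13, adjusted p = 0.0583 with an estimated correlation). The genes the same group had named, which are not independent evidence, were lower in 8 of 9, also adjusted over the list alone (camera adjusted p = 3.85e-12, adjusted p = 0.00558 with an estimated correlation). Actin regulators were higher in 1, lower in 35 and not passed in 43 of 79, with 5 and 43 adjusted over the list alone (camera adjusted p = 6.44e-10, adjusted p = 0.104 with an estimated correlation), and ARPC1A was at -0.94 (SE 0.05). Mesenchymal markers were higher in 2, lower in 21 and not passed in 29 of 52, with 3 and 23 adjusted over the list alone (camera adjusted p = 2.09e-05, adjusted p = 0.177 with an estimated correlation). Of 16 transition factors 4 were lower and 12 not passed, also adjusted over the list alone (camera adjusted p = 0.00376, adjusted p = 0.0627 with an estimated correlation). Matrix genes were higher in 11, lower in 24 and not passed in 34 of 69, with 13 and 28 adjusted over the list alone (camera adjusted p = 0.00436, adjusted p = 0.414 with an estimated correlation). The matrix call ended among genes at a level of 8 or more (camera adjusted p = 0.0938), in a range over 16 alternatives of 0.00178 to 0.414.

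Tubulin genes were higher than in mock in 3, lower in 9 and not passed in 16 of 28, with 4 and 13 adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.617 with an estimated correlation), and TUBB4A was at -1.01 (SE 0.07). This call ended without mock replicate 3 (adjusted p = 0.0609) and among genes at a level of 8 or more (0.143), in a range over 16 alternatives of 0.00694 to 0.617. Interferon genes were higher in 6, lower in 0 and not passed in 45 of 51, with 5 and 0 adjusted over the list alone (camera adjusted p = 0.0256, adjusted p = 0.632 with an estimated correlation), among them EPSTI1 at 0.64 (SE 0.08). The interferon call ended without mock replicate 1 (0.0543) or mimic replicate 1 (0.253) and among genes at a level of 8 or more (0.171), in a range of 0.0013 to 0.632. The other 10 lists did not pass, with camera adjusted p from 0.238 to 0.83. Among them the stress list had a median of 0.01, a mean of -0.05 and a test that pointed lower, and the survival list 0.01, -0.02 and lower. The ACTB control probe sets, which bear on RNA integrity and labelling, differed along with these groups. Their centred 3' minus 5' value averaged -0.18 ± 0.03 in mock, 0.10 ± 0.04 in scrambled and 0.02 ± 0.08 in mimic arrays (SD, n = 3), against 0.03 ± 0.04, 0.01 ± 0.02 and -0.02 ± 0.03 for GAPDH.

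Calls against the controls overlapped. There were 903 genes higher than both controls and 923 lower than both, where independent lists would share 127.2 and 144.2. More genes were higher than lower without mimic replicate 2 (836 and 687), mimic replicate 3 (716 and 690), mock replicate 3 (817 and 751) or scrambled replicate 2 (753 and 740). In 100 simulations of unchanged groups sharing the mimic arrays the highest overlap was 0, which says little, since groups without changes leave few calls to share. By at least 1.5-fold, 112 genes were higher and 76 lower than both controls. The changes correlated across genes at 0.743, against 0.5 in simulations, with a covariance of 0.0252 against 0.00229, and genes are not independent replicates. The mimic arrays are too few to be split between the comparisons, so part of the excess may come from these shared arrays.

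Against the mean of both controls, CDH1 was 10.6-fold higher (log2 change 3.40, SE 0.10, adjusted p = 1.46e-08, and 1.96 with the mean of both probe sets) and OSTM1 3.67-fold lower (SE 0.05). In all, 1738 genes were higher and 1876 lower, of which 154 and 109 changed by at least 1.5-fold. Without mimic replicate 2 there were 1500 higher and 1284 lower. The epithelial list held 35 higher, 0 lower and 26 not passed of 61, with 38 and 0 adjusted over the list alone (camera adjusted p = 6.26e-18, adjusted p = 0.00413 with an estimated correlation). Published targets held 3 higher, 33 lower and 31 not passed of 67, with 4 and 36 adjusted over the list alone (camera adjusted p = 4.45e-12, adjusted p = 0.0679 with an estimated correlation). Actin regulators held 4 higher, 28 lower and 47 not passed of 79, with 9 and 38 adjusted over the list alone (camera adjusted p = 1.81e-07, adjusted p = 0.181 with an estimated correlation). Interferon genes held 13 higher, 1 lower and 37 not passed of 51, with 16 and 1 adjusted over the list alone (camera adjusted p = 6.21e-05, adjusted p = 0.326 with an estimated correlation). Mesenchymal markers held 2 higher, 18 lower and 32 not passed of 52, with 3 and 20 adjusted over the list alone (camera adjusted p = 0.000196, adjusted p = 0.26 with an estimated correlation). Transition factors held 0 higher, 4 lower and 12 not passed of 16, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.0124, adjusted p = 0.108 with an estimated correlation). The genes the same group had named, which are not independent evidence, held 7 lower of 9, with 8 adjusted over the list alone (camera adjusted p = 2.1e-11, adjusted p = 0.00413 with an estimated correlation). TUBB3 did not pass (log2 change -0.13, adjusted p = 0.0769) but did without mimic replicate 1 (-0.18, adjusted p = 0.0212, the lowest of 16 alternatives that reached 0.275).

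The scrambled control was compared with mock to measure the effect of transfecting an RNA that has no intended target. IGSF5, an immunoglobulin superfamily gene, was 1.80-fold higher than in mock (SE 0.10, adjusted p = 0.000992), and DICER1, the nuclease that makes microRNAs, 1.48-fold higher (log2 change 0.56, SE 0.05, adjusted p = 0.000297). LRRC4B was 2.43-fold lower (SE 0.16), the stress-induced cytokine gene GDF15 1.82-fold lower (SE 0.06), the collagenase gene MMP1 1.71-fold lower (SE 0.07) and EMP2 1.70-fold lower (SE 0.06). PTBP2, ENPP5, CHIC1, NHLRC3 and ZFYVE26 were 1.39-fold to 1.45-fold higher, and STEAP3, HMOX1 and SPOPL 1.65-fold to 1.68-fold lower. Neither CDH1 (log2 change 0.29, adjusted p = 0.149) nor ZEB1 (0.00, adjusted p = 0.973) passed. In all, 551 genes were higher and 1039 lower, of which 1 and 35 changed by at least 1.5-fold.

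With the mean of all probe sets the log2 changes of GDF15 (-0.26), DICER1 (0.29), PTBP2 (0.32) and CHIC1 (0.31) were over 1.5 times smaller, and after quantile normalization those of PTBP2 (1.09), ENPP5 (0.81) and NHLRC3 (0.73) were larger. The calls of this comparison depended on single arrays. Without mock replicates 1, 2 and 3 in turn the counts were 224, 236 and 413 higher with 563, 592 and 625 lower. Without scrambled replicates 1, 2 and 3 in turn they were 357, 291 and 218 higher with 663, 712 and 557 lower. Of the named genes, IL7 (log2 change 0.52, adjusted p = 0.0448) lost its call without any 1 of the mock or scrambled arrays or mimic replicate 2, with an adjusted p of up to 0.138 over 17 alternatives that began at 0.00776. It was also lost with the replicate block (limma adjusted p = 0.0627) and without both mock replicate 3 and mimic replicate 1 (0.0609). AKT1S1 (-0.75, adjusted p = 0.0392) lost its call without any 1 of the mock or mimic arrays, with an adjusted p of up to 0.1 in these and a range of 0.00248 to 0.115 over 17 alternatives, and its log2 change was -0.44 without scrambled replicate 2. Its call also ended with the mean of its probe sets (limma adjusted p = 0.0522), with only the arrays compared (0.0782) and without both mock replicate 3 and mimic replicate 1 (0.115). NHLRC3 lost its call with the mean of its probe sets (adjusted p = 0.398, the highest of 17 that began at 0.000649).

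By camera with its preset correlation, 10 lists passed as lower in scrambled control than in mock cells, and with an estimated correlation none of them passed. Beside them, the ACTB 3' minus 5' value was 0.28 higher in scrambled than in mock arrays, with no overlap of the groups, and that of GAPDH was -0.02 apart with overlap. This holds beside each of the 10 lists. Matrix genes were higher in 2, lower in 16 and not passed in 51 of 69, with 2 and 20 adjusted over the list alone (camera adjusted p = 2.96e-05, adjusted p = 0.364 with an estimated correlation), among them FN1 at -0.47 (SE 0.06) and LAMB3 at -0.35 (SE 0.05). Actin regulators were lower in 12 of 79 and not passed in 67, with 14 adjusted over the list alone (camera adjusted p = 0.000135, adjusted p = 0.367 with an estimated correlation). Stress genes were lower in 7 of 26 and not passed in 19, with 7 adjusted over the list alone (camera adjusted p = 0.000384, adjusted p = 0.39 with an estimated correlation), among them DNAJB1 at -0.51 (SE 0.05). Cholesterol and fatty acid genes were lower in 4 of 27 and not passed in 23, with 1 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.000483, adjusted p = 0.364 with an estimated correlation), among them ACLY at -0.43 (SE 0.05). Mesenchymal markers were higher in 2, lower in 13 and not passed in 37 of 52, with 3 and 16 adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.367 with an estimated correlation).

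Interferon genes were lower in scrambled control than in mock cells in 10 of 51 and not passed in 41, with 1 higher and 14 lower adjusted over the list alone (camera adjusted p = 0.00141, adjusted p = 0.39 with an estimated correlation), among them IRF9 at -0.60 (SE 0.10) and EPSTI1 at -0.39 (SE 0.08). Tubulin genes were lower in 6 of 28 and not passed in 22, with 6 adjusted over the list alone (camera adjusted p = 0.00297, adjusted p = 0.39 with an estimated correlation), among them TUBB4A at -0.53 (SE 0.07) and TUBB3 at -0.31 (SE 0.05). TGF-beta genes, GDF15 among them, were lower in 4 of 34 and not passed in 30, with 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00395, adjusted p = 0.463 with an estimated correlation). Published targets were higher in 3, lower in 11 and not passed in 53 of 67, with 6 and 15 adjusted over the list alone (camera adjusted p = 0.00915, adjusted p = 0.39 with an estimated correlation). Without mock replicate 3 the TGF-beta and published target lists did not pass (0.0697 and 0.0772), nor did they at a level of 8 or more (0.371 and 0.254), in ranges of 0.00128 to 0.463 and 0.000277 to 0.39 over their alternatives. The genes the same group had named, which are not independent evidence, were lower in 4 of 9 and not passed in 5, with 5 adjusted over the list alone (camera adjusted p = 0.000483, adjusted p = 0.138 with an estimated correlation). The other 9 lists did not pass, with camera adjusted p from 0.0802 to 0.925. Among them the epithelial list had a median of 0.03, a mean of 0.01 and a test that pointed lower, and the Notch list 0.03, -0.02 and lower.

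Of the 1514 genes higher with the mimic than with the scrambled control, 356 (23.5%) were also called lower in scrambled than in mock cells, and of the 1399 lower genes 186 (13.3%) were called higher there. SPOPL and EMP2 were among the former, with log2 changes of 0.93 and 0.83 for mimic against scrambled control and 0.20 and 0.07 for mimic against mock. These comparisons share the scrambled arrays, so chance values enter both in opposite directions.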

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

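The tests of the splits were planned, and those of the scrambled and mock difference, of the interferon list and of the probe sets that deviate together were chosen after the result was seen.

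Probe sets outside the gene tests also changed. Of 11721 probe sets with no gene symbol, 510 (4.35%) were called between mimic and scrambled control, against 228 (1.95%) between scrambled control and mock. Of 1801 with several symbols, 148 (8.22%) were called, against 89 (4.94%).

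Splits of the arrays bear on chance. The 9 arrays can be split into 3 and 6 in 84 ways. Only the real split reached its count of 2579 genes for the mimic against both controls. Each split was fitted with 2 groups, so the difference between the controls entered the spread. The count therefore differs from the 1738 higher and 1876 lower of the fit with 3 groups. The highest other split, which sets the mock arrays apart, called 909, and the one that sets the scrambled arrays apart called 362. This speaks against chance only if the arrays are independent samples, which the labels do not say. The splits relabel the same arrays, so they cannot exclude a difference between single cultures or batches. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Fitted on those arrays alone, the real splits called 2415 genes for mimic against scrambled control, 3243 for mimic against mock and 1456 for scrambled control against mock, and the highest other split called 0 in each, so that 1 split of 10 reached the real count.

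Scrambled control and mock differed in 1590 genes. The deviating mock array is argued against as the whole cause, since 57.9% of the genes were called the same way without mock replicate 3 and mimic replicate 1. Leaving out any array loses calls. Of the 551 higher and 1039 lower genes, 192 and 545 stayed called without mock replicate 1 and 208 and 574 without mock replicate 2. Without mock replicate 3, the deviating array, 325 and 597 stayed. The loss is therefore not particular to that array. Transfection shared by both transfected groups cannot be told apart from other causes: 34.1% of the genes (binomial interval 31.8 to 36.5) were called back towards mock in mimic against scrambled control, against at most 17.7% in 50 simulations, but these assume mimic effects unrelated to transfection. The binomial interval counts genes as independent, which they are not, so it does not measure the spread between arrays. On the other side, 32.8% of the 551 higher and 42.8% of the 1039 lower genes were called in mimic against mock in the same direction and not in mimic against scrambled control, and the median changes against mock were 0.24 and -0.28 for the scrambled control and 0.13 and -0.19 for the mimic. These genes were chosen by their change between scrambled control and mock. Both changes share the mock arrays, so chance values in mock enter them in the same direction. These shares and medians therefore decide nothing about transfection. A 3' to 5' difference in labelling stays open, since ACTB differed by 0.28 between these groups and GAPDH by -0.02 and 2 control genes decide nothing, and so does a response to the scrambled sequence itself, which was not tested. A difference in time was not tested either, because the labels give none for mock cells.

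Of 51 interferon genes, 18 were called higher with the mimic than with the scrambled control, 1 lower and 32 did not pass (camera adjusted p = 7.37e-07, adjusted p = 0.265 with an estimated correlation). Noise of dim probe sets is argued against, since the 23 members at a level of 8 or more had a median log2 change of 0.22, and 12 of them were called higher. The bootstrap intervals in this paragraph (0.13 to 0.30 for this median) resample genes. Genes are not independent replicates, so these intervals do not measure the spread between arrays. Against mock, 6 members were called higher with the mimic, where random lists of the same levels gave 4.64 on average and up to 9 within their 95% range, and 10 were called lower in the scrambled control, where random lists gave 2.90 and 6. A fall in the scrambled arrays and a rise in the mimic arrays cannot be told apart as sole causes, because neither call holds with an estimated correlation (adjusted p = 0.632 and 0.39) and the bootstrap interval of neither median holds 0 (0.03 to 0.10 and -0.15 to -0.02). A candidate explanation that joins a fall in the one and a small rise in the other stays a hypothesis.

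Probe sets deviated together in mock replicate 3 and mimic replicate 1, where 148 lay more than 0.4 from their group's mean with the same sign, 133 of them lower, and 0 with opposite signs, which independent noise of dim probe sets would give as often. No other pair from different groups shared more than 33 with the same sign, while 4 pairs that hold 1 of these arrays had 35 to 68 with opposite signs, and deviations in a group sum to 0, so these are not independent of the first. MATR3, chosen after its values were seen, was at -2.24 and -2.19 on 1 of its probe sets, while the other 7 arrays lay from -0.02 to 0.11. A change of the whole gene's RNA is argued against for the 71 probe sets whose gene had another at a level of 4 or more, since those others deviated by a median of -0.012 (bootstrap interval -0.023 to 0.003) where the first deviated by 0.66, while it stays open for the other 77, and 48% of the 148 had no single gene symbol, against 24.8% of all. A batch of labelling or hybridisation for these 2 arrays, with its 148 probe sets, cannot be told apart from a difference in RNA processing, because the labels used here give no batch, and no biological difference between the arrays beyond the gene's RNA was tested.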

How the results depend on the processing

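Filters on the recovered level, the fit without mock replicate 3 and mimic replicate 1 and every alternative for the overlap were chosen after seeing the data. The planned low-value filters, the pseudocount and the seed search were not run. No named gene or list that passed, as reported or in an alternative, had opposite directions in these. The balance of calls did turn for mimic against scrambled control, from 1514 higher and 1399 lower to 1293 and 1451 at level 8 or more, 1153 and 1314 without mimic replicate 1, and 1125 and 1258 without both deviating arrays. For mimic against both controls it turned from 1738 and 1876 to 1500 and 1284 without mimic replicate 2 and to 154 and 109 at 1.5-fold. In the overlap it turned from 903 and 923 to 836 and 687 without mimic replicate 2, 716 and 690 without mimic replicate 3, 817 and 751 without mock replicate 3, and 753 and 740 without scrambled replicate 2. It also turned there to 800 and 766 with the mean of all probe sets, 785 and 777 with only the arrays compared, and 112 and 76 at 1.5-fold. Medians of 3 lists that did not pass went from 0.01 to -0.01 or back without both deviating arrays: small RNA machinery against the scrambled control, survival against mock and cell cycle in scrambled control against mock. The cause of the changes below was not tested unless named. Signal over background, which sets what the arrays can detect, is not known. The replicate number did not pair the arrays: deviations of arrays with the same number correlated at -0.153 to 0.118, and not every array correlated best with its own number (mock replicate 3 did with mimic replicate 1, at 0.243). With the replicate block the counts stayed within 1.5 times, for example 1371 higher and 1233 lower for mimic against scrambled control, of which 1325 and 1185 were called without it. Centring each array moved next to nothing by construction, since the deposited arrays already had medians of 0, so it says nothing about scaling. Of 74 called changes of named genes against the scrambled control, 22 were over 1.5 times smaller on the log2 scale with the mean of all probe sets and 6 after quantile normalization. The latter narrows the wider values of the mimic arrays by construction.

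A fold of at least 1.5, stricter by construction, left 187 higher and 111 lower for mimic against scrambled control, 151 and 156 against mock, 1 and 35 for scrambled control against mock, and 154 and 109 against both controls. Every probe set, with more features tested, gave 2466 and 2264, 2771 and 3814, and 2973 and 3395 for the mimic comparisons in that order, and 1374 and 1532 in the overlap. For scrambled control against mock, array weights gave 1012 higher, genes at level 8 or more 844 higher, and the fit without both deviating arrays 647 lower. Leaving out 1 array gave 218 to 552 higher and 557 to 1110 lower there. All other settings kept the 8 counts and the overlap within 1.5 times.

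With an estimated correlation 27 list calls were lost. Against the scrambled control the adjusted p became 0.115 for published targets, 0.613 mesenchymal, 0.497 actin, 0.265 interferon and 0.666 stress. Against mock it was 0.0583 published, 0.0627 transition factors, 0.177 mesenchymal, 0.104 actin, 0.414 matrix, 0.617 tubulin and 0.632 interferon. For scrambled control against mock it was 0.39 published, 0.138 same group, 0.367 mesenchymal, 0.367 actin, 0.364 matrix, 0.39 tubulin, 0.463 TGF-beta, 0.39 interferon, 0.364 cholesterol and 0.39 stress. Against both controls it was 0.0679 published, 0.108 transition factors, 0.26 mesenchymal, 0.181 actin and 0.326 interferon.

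By fry, which does not compare a list with other genes, transition factors passed against the scrambled control (6.58e-05) and in scrambled control against mock (0.0161), small RNA machinery against mock (0.0168), and matrix, tubulin and small RNA machinery against both controls (0.0348 each). Interferon against mock (0.0946) and, in scrambled control against mock, published targets (0.0671), TGF-beta (0.0728) and interferon (0.0781) did not. At level 8 or more, transition factors passed against the scrambled control (0.00239), and these did not: mesenchymal there (0.162), matrix (0.0938), tubulin (0.143) and interferon (0.171) against mock, and published targets (0.254), TGF-beta (0.371) and stress (0.0594) in scrambled control against mock. The mean of all probe sets lost mesenchymal and stress against the scrambled control (0.0622 each) and gained transition factors in scrambled control against mock (0.035). Quantile normalization lost mesenchymal (0.0589). Without both deviating arrays stress against the scrambled control (0.0594), interferon against mock (0.242) and published targets in scrambled control against mock (0.0656) were lost, and cholesterol against mock was gained (0.0469).

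Leaving out 1 array moved the adjusted p across the threshold for 7 lists: against the scrambled control mesenchymal (0.0131 to 0.0688), TGF-beta (0.0344 to 0.287) and cholesterol (0.046 to 0.576), against mock tubulin (0.0124 to 0.0609) and interferon (0.0013 to 0.253), and in scrambled control against mock published targets (0.00178 to 0.0772) and TGF-beta (0.00128 to 0.0697). Of 155 changes of named genes, 23 crossed the threshold in at least 1 setting, 14 of them among the 83 for mimic against scrambled control.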

Other observations

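The genes in these paragraphs stand outside the fixed lists and were chosen after their values were seen, and no group of them was tested. The basal keratin gene KRT15 had log2 changes of 1.56 with the mimic against the scrambled control and 1.40 against mock (SE 0.10 each), and the epithelial sodium channel gene SCNN1A of 1.41 and 1.20 (SE 0.05). The sciellin gene SCEL rose by 0.82 and 0.86 (SE 0.13), the filaggrin gene FLG by 0.71 and 0.82 (SE 0.06), and the transcription factor gene KLF5 by 0.81 and 0.65 (SE 0.06). The glucose transporter gene SLC2A3 rose by 1.29 and 1.39 (SE 0.05), the long noncoding RNA UCA1 by 1.56 and 1.40 (SE 0.09), and the chemokine gene CXCL8 by 0.83 and 0.81. Each of these changes passed the adjusted threshold against both controls.

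The heparan sulfate sulfotransferase genes HS3ST3B1 and HS6ST2 had log2 changes of -1.03 and -0.91 against the scrambled control and -0.59 and -0.77 against mock, and the fucosyltransferase gene FUT9 of -0.85 and -0.74. HS3ST3B1 was also higher in scrambled than in mock cells (0.44). In the other direction, the sialyltransferase gene ST6GALNAC5 rose by 1.43 and 1.40 and the sulfotransferase gene HS3ST6 by 0.67 and 0.60. The chemokine gene CXCL12 fell by 0.82 and 0.74, and the chaperone gene HSP90AB1 by 0.82 and 0.88.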
